A study of Mus musculus with 12 samples.

How the data were processed

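Mouse acute myeloid leukemia driven by the fusion oncogene MLL-AF9 was profiled on 12 one-colour expression arrays, in 4 groups of 3. Per the labels' protocols, recipient mice irradiated with 10 Gy received 50000 MLL-AF9 expressing progenitor and stem cells, either wild type for the energy-sensing kinase AMPK (floxed alleles) or AMPK-deficient (deleted alleles), and bone marrow was taken at the onset of leukemia in each recipient. From each marrow fraction 5000 cells were sorted, either all GFP-positive cells (whole leukemia) or the L-GMP fraction, leukemic granulocyte-macrophage progenitors that were also lineage-negative, c-Kit-positive, CD16/32-positive and CD34-positive. Per the labels, RNA was amplified and biotin-labelled with NuGEN whole-transcript kits. The labels do not say that the replicates of a group come from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

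The deposited values are linear intensity values per probe set, from 17.96 to 9108.2 over 33794 probe sets, and the array medians lay between 36.9 and 39.3. The medians and quartiles of the 12 arrays lay close together, and the software, background correction and normalization are not given in the sources used here. The values were taken to log2 with no further scaling and no pseudocount. Gene symbols came from the platform annotation, in which 23521 probe sets had 1 symbol, 1814 had several and 8459 were not listed and stay unnamed here. Of the gene identifiers, 99.2% were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols; that table was otherwise used only to find neighbouring genes. Each gene was represented by its single-symbol probe set with the highest mean, and genes with a mean log2 value below 4.72, the lowest 25% of probe sets, were left out, which removed 4431 genes and kept 17749. The 10273 probe sets with several symbols or none were tested apart, and 0 were called in any of the 5 comparisons by limma (lowest adjusted p = 0.266).

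Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with lmFit and eBayes on 1 mean per group over all 12 arrays, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were knockout against wild type in L-GMP and in whole leukemia, L-GMP against whole leukemia in each genotype, and the genotype-by-population interaction. The spread had 8 residual degrees of freedom and 2.36 prior ones. Of the 37 gene lists, which held 736 genes with 644 of them tested, 36 were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 36 lists; the sex-linked list was only described. Each called list is also given with camera's estimated correlation, and fry was run as an alternative. The groups, the tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except for 3 added alternatives, namely leaving out both number-2 knockout arrays, leaving out both number-2 wild-type arrays and a block by genotype and number, which were chosen after seeing the data.

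The rule for named genes took, in each comparison, the AMPK catalytic subunit genes Prkaa1 and Prkaa2, the other subunits as a group, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap, filled where fewer passed to the 5 genes of lowest p in each direction and named as not passing, up to 4 members of lowest p of each called or relevant list, and the sorting gate and sex-linked genes. Predicted genes and clone names were counted and not named, except the 1 called gene, 1700080G11Rik, which was chosen after its values were seen. Folds are differences of mean log2 intensity, and compression near background makes them smaller for dim genes.

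The scripts were checked on simulated arrays for the 17749 genes with 200 genes changed. In the simulated L-GMP genotype comparison 10% of changes of 0.5 log2, 68% of changes of 1, 96% of changes of 2 and 98% of changes of 3 were recovered, with 6 false calls among 142. In the simulated whole leukemia comparison these shares were 20%, 74%, 94% and 100%, and in the simulated interaction 2%, 44%, 84% and 98%. In the simulated comparisons of L-GMP with whole leukemia a change of 1 log2 was recovered for 72% of genes in the wild type and 78% in the knockout. A list shifted by 1 log2 was called in each simulated comparison, with 0 of the other lists called. The simulated noise was normal and held no correlation between genes. The 200 changed genes also eased the adjusted threshold, since 142 genes were called in the simulated L-GMP comparison against 1 in the real data. The shares recovered therefore do not measure the power in the real data.

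Whether equal replicate numbers pair samples was checked from the correlation of deviations from group means. Wild-type whole leukemia and wild-type L-GMP arrays of numbers 1, 2 and 3 correlated at 0.36, 0.62 and 0.3, each best with its own number, and the numbers were taken to pair these 6 arrays from the data, since no label ties a number to a mouse. With the replicate block, which takes a number as shared by both genotypes, 0 genes and 8 lists were called in that comparison, the counts found without it. That block is not the paired test, since numbers did not pair across genotypes. The block by genotype and number, chosen after seeing the data, pairs within a genotype, and it ended none of these 8 calls. The other pairs of groups did not meet the criterion.

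The alternatives were quantile normalization, median centring, other filters on dim genes, a trended and robust variance, array weights, the mean of all probe sets of a gene, the compared groups alone, replicate blocks, other list tests and leaving out each array in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.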

Results

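The series asks how loss of AMPK alters gene expression in MLL-AF9 leukemia, in the sorted L-GMP fraction, which the submitters equate with leukemia-initiating cells, and in the leukemia as a whole. It holds 12 arrays, 3 each of wild-type and knockout whole leukemia and of wild-type and knockout L-GMP. Pearson correlations between arrays ranged from 0.902 to 0.986. Knockout whole leukemia array 2 stood apart, at 67.4 on the first principal component (32.4% of the variance) against -24.2 to 18.5 for the other 11 arrays. Without it the lowest correlation was 0.943. On the second component (17% of the variance) knockout L-GMP array 2 lay at -41.3, against -19.6 to 21.8 for the other 11 arrays. The median standard error of a difference between 2 groups was 0.15 log2, with a 95% half-width of 0.34. With 3 arrays against 3, an exact two-sided permutation test of a single gene cannot go below p = 0.1.

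Prkaa1, which encodes the catalytic alpha 1 subunit of AMPK (probe set 17309907), measured 7.0 ± 0.27 log2 units (SD, n = 3) in knockout L-GMP and 8.15 ± 0.17 in wild-type L-GMP, a difference of -1.15 (SE 0.24, 95% interval -1.68 to -0.62, 0.452-fold). In whole leukemia it measured 7.27 ± 0.27 in the knockout and 8.25 ± 0.49 in the wild type, a difference of -0.98 (SE 0.24, 0.508-fold). Every knockout array lay below every wild-type array of its population, 3 of 3 in both, although neither difference passed limma over all genes (adjusted p = 0.622 and 0.592). Within the list of 7 AMPK subunits Prkaa1 was the 1 member called in each population when adjusted over the list alone, and 0 members were called over all genes. Prkaa2, encoding the alpha 2 subunit (probe set 17427746), lay near background at 4.86 ± 0.03 in knockout and 4.88 ± 0.15 in wild-type L-GMP, and at 4.86 ± 0.05 and 4.76 ± 0.09 in whole leukemia. The beta and gamma subunit genes, Prkab1, Prkab2, Prkag1, Prkag2 and Prkag3, differed between genotypes by -0.10 to 0.22 in L-GMP and by -0.42 to 0.49 in whole leukemia, all at adjusted p = 0.829 or above. The labels do not say which part of which subunit gene was deleted, so a probe set that lies outside that part would not measure the deletion.

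In L-GMP the comparison of knockout with wild type asks what AMPK loss alters in the leukemia-initiating fraction. By camera with the preset correlation, knockout L-GMP had lower levels of monocyte and macrophage genes, MLL-AF9 target genes and cell cycle genes, and higher levels of granulocyte-macrophage progenitor, antioxidant and pentose phosphate pathway genes. All of these calls were lost with an estimated correlation (adjusted p = 0.761), and the cell cycle lists turned upward without knockout L-GMP array 3 (0.997 for G2/M and 0.864 for G1/S). 1700080G11Rik, an uncharacterised transcript, fell from 7.5 ± 0.28 to 4.82 ± 0.53 log2 units (SD, n = 3). Stag3, a subunit of meiotic cohesin (probe set 17443833), measured 8.58 ± 0.63 in the wild type and 5.80 ± 0.34 in the knockout. 1700080G11Rik was the 1 gene called by limma among 17749 (log2 difference -2.67, SE 0.28, 0.157-fold, adjusted p = 0.0314, lower in 3 of 3 knockout arrays). Its knockout mean of 4.82 lay near the cut for dim genes (4.72), so the size of the fall may be understated. Higher in the knockout, 0 genes were called. At an unadjusted p under 0.05 there were 733 genes, 408 higher and 325 lower, where 887 would be met by chance. The arrays of both genotypes did not overlap for 9.48% of genes, where chance gives 10%. The call rested on every array but 2. Without wild-type whole leukemia array 2 its adjusted p was 0.0201 and without knockout L-GMP array 1 it was 0.00945, where Cox6b2 was called too. Without any one of the other 10 arrays it lay between 0.0646 and 0.316. With array weights limma called 4 genes, 3 lower and 1 higher, the last being Msantd3 (1.64, adjusted p = 0.0144). Limma called, with a trended and robust variance 2, with the 2 compared groups alone 0 and with no filter on dim genes 0 (lowest adjusted p = 0.0656).

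The other genes of lowest p did not pass. Those with lower values in knockout L-GMP were Stag3 (-2.77, SE 0.37, adjusted p = 0.145), the microtubule-associated ubiquitin ligase gene Mid1 (-0.88, SE 0.12, adjusted p = 0.167), Get3, which encodes an ATPase of membrane protein insertion (-0.85), Sdccag8 (-0.93) and the clathrin light chain gene Cltb (-0.75). Those with higher values were Msantd3 (1.60, SE 0.25, adjusted p = 0.276), the deubiquitinase gene Usp24 (0.63), Btbd9 (0.50), the tumor necrosis factor receptor family member Tnfrsf26 (1.31) and F2rl3, encoding a thrombin receptor (0.52). In each of these 10 genes the 3 knockout arrays lay on one side of the 3 wild-type arrays. Of the genes for the sorting gate, Cd34 (-0.09, SE 0.37), Fcgr3 (0.07) and Fcgr2b (-0.05) differed little. Kit, encoding the c-Kit receptor, had a difference of 1.08 (SE 0.48, adjusted p = 1), with 8.64 ± 0.90 in the knockout and 7.56 ± 0.55 in the wild type. The Y-linked genes Eif2s3y, Kdm5d and Uty differed by -0.22 to 0.02. Xist, the RNA of X inactivation, measured 5.32 ± 0.57 in the knockout and 4.63 ± 0.03 in the wild type.

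**Figure D1:**
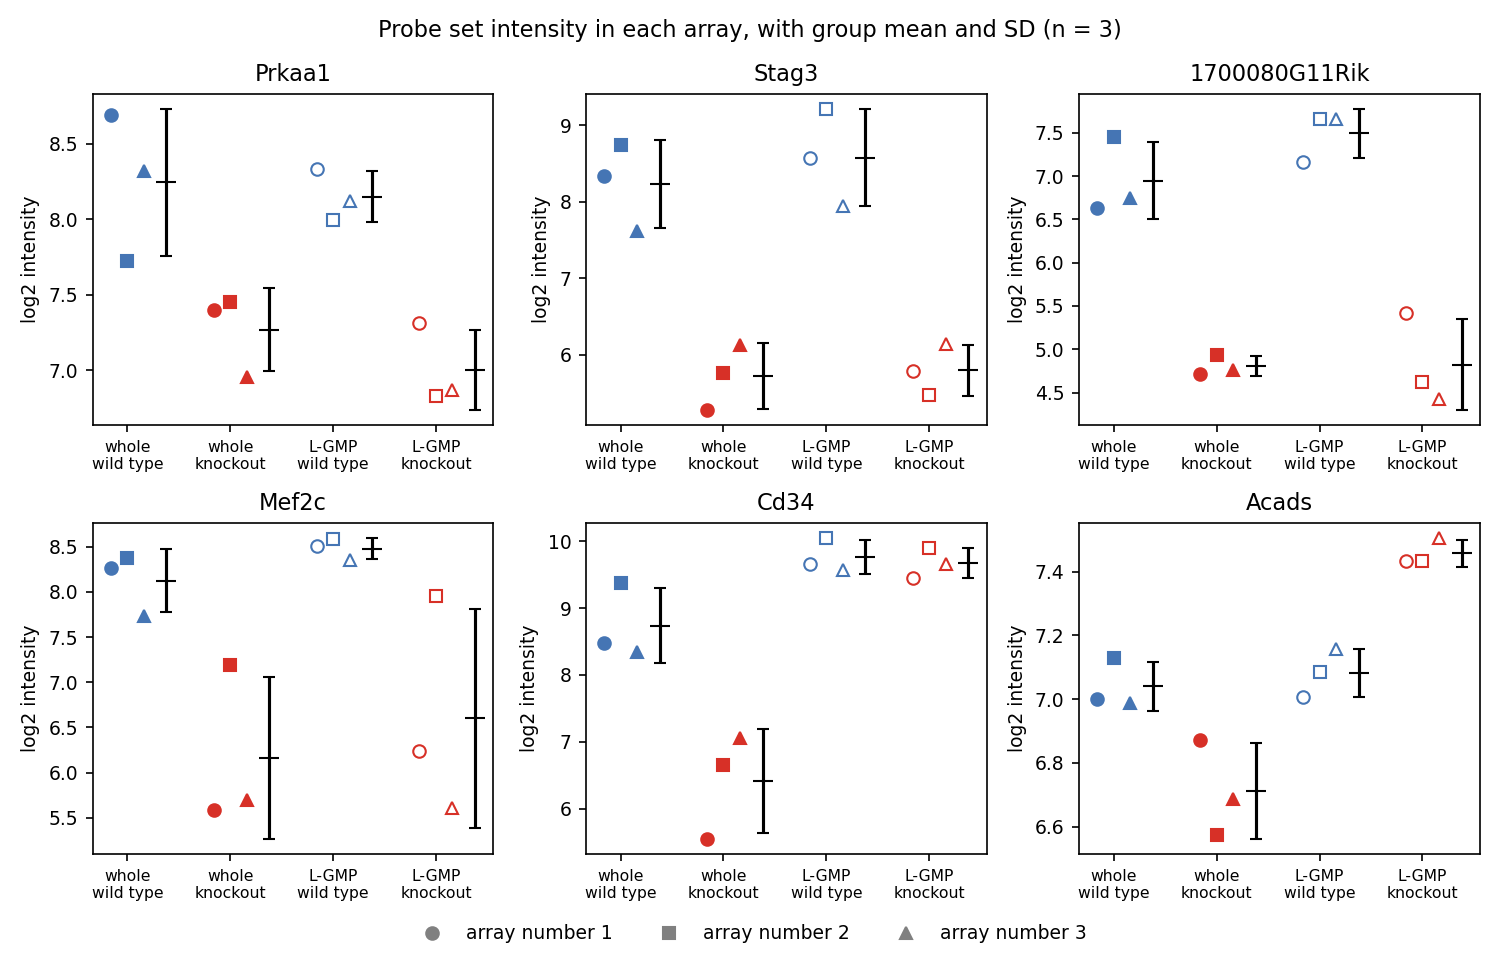
Log2 intensity of 6 genes in each of the 12 arrays, by group (filled symbols for whole leukemia, open for L-GMP, blue for wild type, red for knockout; the symbol gives the array number), with bars for the group mean and SD (n = 3). Prkaa1, Stag3 and 1700080G11Rik lay lower in all knockout arrays of both populations, and Cd34 differed by genotype in whole leukemia (6.41 against 8.74) but little in L-GMP (9.67 against 9.76).

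Camera with the preset correlation called 9 of 36 lists in L-GMP, 3 higher and 6 lower in the knockout. With an estimated correlation 0 were called, each of the 9 at an adjusted p = 0.761 with an estimated correlation, and fry called 0. Monocyte and macrophage genes were lower, with 19 of 22 members below the wild type, among them the macrophage gene Mpeg1 (-0.95, SE 0.29) and the fibronectin gene Fn1 (-2.41, SE 0.78) (adjusted p = 0.000312). This call held without each of the 12 arrays, at 1.65e-06 to 0.0218. MLL-AF9 target genes were lower in 12 of 17 members, led by the transcription factor genes Mef2c (-1.88, SE 0.56), Hoxa10 (-0.53) and Hoxa5 (-0.78) (adjusted p = 0.0108), but not past the threshold without wild-type L-GMP array 2 (0.0838) or knockout L-GMP array 2 (0.114), or with array weights (0.236). Mef2c measured 7.95 in knockout L-GMP array 2 against 6.24 and 5.61 in arrays 1 and 3. When both number-2 knockout arrays were left out, its difference of -2.55 was the 1 gene call by limma (adjusted p = 0.0291). Those arrays were chosen after seeing the data and held the highest knockout values of Mef2c. Their removal enlarges the difference, so this call cannot stand as support for it. Granulocyte-macrophage progenitor genes were higher in 13 of 18 members, with the granule protease gene Prss57 (1.51, SE 0.49), the granule protein gene Nkg7 (2.50, SE 0.86) and Ms4a3 (1.26) (adjusted p = 0.0124; 0.0838 without wild-type L-GMP array 2). Members of these lists called over all genes numbered 0, as did members of these 3 lists adjusted over the list alone.

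All 24 G2/M genes were lower in knockout L-GMP, such as Tpx2 (-0.55), Bub1 (-0.76) and Ccna2 (-0.84) (adjusted p = 0.00125), as were 19 of 22 G1/S genes, such as Pcna (-0.32) (adjusted p = 0.0218), and 16 of 20 DNA repair genes, such as Atr (-0.54) (adjusted p = 0.0255). These 3 lists turned upward without knockout L-GMP array 3, whose G2/M mean was 6.75 against 7.73 to 8.51 in the other 5 L-GMP arrays (adjusted p = 0.997, 0.864 and 0.993), and were not called without wild-type L-GMP array 2 (0.0767, 0.334 and 0.381). With array weights the G1/S (0.338) and DNA repair (0.137) lists were not called. Interferon response genes were lower in 18 of 24 members, with Mx2 at -0.90 (SE 0.62) and Ifit1 at -0.66 (SE 0.59) (adjusted p = 0.0255). Wild-type L-GMP array 2 had an interferon mean of 7.77 against 5.62 to 6.11 in the other 5 L-GMP arrays. Without it the list turned upward (adjusted p = 0.338), and it was also not called without knockout L-GMP array 2 (0.114) or 3 (0.0678). Nor was it called with array weights (0.36), quantile normalization (0.0504) or the lowest 50% left out (0.0599). Antioxidant and glutathione genes were higher in 16 of 23 members, with the thioredoxin reductase gene Txnrd1 (0.68, SE 0.15) called when adjusted over the list alone (adjusted p = 0.0494). Pentose phosphate and NADPH genes were higher in 10 of 12 members, among them the transaldolase gene Taldo1 (0.32, SE 0.13) and Idh2 (0.80, SE 0.45) (adjusted p = 0.0494). Both calls were lost without whole leukemia arrays wild-type 1, 2 or 3 or knockout 3, or L-GMP arrays wild-type 1 or knockout 1 or 2. The adjusted p was then up to 0.431 for the first and 0.378 for the second, and the second was lost also without wild-type L-GMP array 2 (0.0769). They were lost too with the lowest 50% left out (0.0552 for both), a trended and robust variance (0.0575 for both) and the mean of all probe sets (0.0535 and 0.0567). Array weights ended the first (0.142) and no filter on dim genes the second (0.0946). For these 6 lists the adjusted p with an estimated correlation was 0.761.

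Of the metabolic lists, only that of pentose phosphate and NADPH genes was called in L-GMP by camera (adjusted p = 0.0494). The other metabolic lists were not called, glucose transport and glycolysis genes narrowly. Glucose transport and glycolysis genes had a mean difference of -0.09 (adjusted p = 0.053), with the triose phosphate isomerase gene Tpi1 at -0.54 and the glucose transporter gene Slc2a6 at -0.50. Fatty acid oxidation genes had one of 0.16 (adjusted p = 0.135), with the acyl-CoA dehydrogenase gene Acads (0.37, SE 0.09) called when adjusted over the list alone. Fatty acid synthesis (0.17, adjusted p = 0.165), the tricarboxylic acid cycle (0.11, 0.165), cholesterol synthesis (-0.02, 0.264), oxidative phosphorylation (-0.01, 0.451), mitochondrial biogenesis (0.01, 0.662) and autophagy and lysosome genes (0.03, 0.77) followed. The list of AMPK kinases and substrates had a mean difference of 0.09 (adjusted p = 0.264), and the unfolded protein response one of 0.13 (0.165). The ATF4 and amino acid response had one of 0.05 (0.489), p53 targets one of 0.00 (0.339), hypoxia genes one of -0.03 (0.287), and MYC targets one of 0.03 (0.709). Mast cell, basophil and eosinophil genes had a mean difference of 0.70 (adjusted p = 0.0569). In knockout L-GMP array 2 the list mean was 7.93 against 5.84 to 6.22 in the other 5 L-GMP arrays and Prg2, the eosinophil major basic protein gene, measured 11.92. Of the other cell type lists, megakaryocyte genes had a mean difference of 0.14 (adjusted p = 0.102), stem and progenitor genes one of 0.18 (0.165) and stromal genes one of 0.11 (0.264). Neutrophil genes (0.24, 0.451), erythroid genes (0.24, 0.662), B cell genes (0.05, 0.632), T and NK genes (0.04, 0.868) and antigen presentation and dendritic cell genes (-0.11, 0.338) were not called. Nor were the sorting gate list (0.25, 0.51), AMPK subunits (-0.15, 0.264), immediate early genes (0.14, 0.529) and inflammatory cytokine genes (-0.05, 0.437). Without wild-type L-GMP array 2 the number of called lists was 3, and without both number-2 wild-type arrays it was 4.

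In whole leukemia the comparison of knockout with wild type asks the same of the bulk of leukemic cells. By camera with the preset correlation, knockout whole leukemia had lower levels of monocyte genes, MLL-AF9 target genes and hypoxia genes, and higher levels of erythroid and neutrophil genes, both highest in knockout array 2. All of these calls were lost with an estimated correlation (adjusted p = 0.455 or above), and the hypoxia call also without wild-type array 3 or knockout array 2. Cd34 measured 6.41 ± 0.78 log2 units (SD, n = 3) in the knockout and 8.74 ± 0.56 in the wild type, a difference of -2.32 (SE 0.37, 0.2-fold), lower in 3 of 3 knockout arrays, and did not pass (adjusted p = 0.478). Stag3 (-2.50, SE 0.37, adjusted p = 0.358) and 1700080G11Rik (-2.14, SE 0.28, adjusted p = 0.242) had differences of a size like those in L-GMP and did not pass either. Limma called 0 genes, with a trended and robust variance or array weights 0 as well. There were 1059 genes with an unadjusted p under 0.05, 431 higher and 628 lower, where 887 would be met by chance. The arrays of both genotypes did not overlap for 11.2% of genes (10% by chance). Without wild-type whole leukemia array 3 the 1 gene called was Mertk (-1.95, adjusted p = 0.0302), and without wild-type L-GMP array 2 it was Dennd5b (-2.40, adjusted p = 0.0294). When both number-2 knockout arrays were left out, it was Mef2c (-2.48, adjusted p = 0.0366). Mef2c was highest among the knockouts in the arrays left out, so their removal enlarges the difference and that call cannot support it.

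Among the remaining genes of lowest p, none of which passed, those with lower values in knockout whole leukemia were Rad9a of the DNA damage checkpoint clamp (-0.47, SE 0.08, adjusted p = 0.478), the focal adhesion gene Tns1 (-1.37, SE 0.23) and Dennd5b (-2.40, SE 0.42). Those with higher values were the endothelial lipase gene Lipg (0.52), the kinase gene Braf (0.81, SE 0.16), N4bp2l2 (0.45), the ketone body enzyme gene Oxct2a (0.69) and Msantd3 (1.15, SE 0.25, adjusted p = 0.497). Of the gate genes other than Cd34, Fcgr2b (-0.57), Fcgr3 (-0.33) and Kit (0.50) had adjusted p-values of 0.829, 0.829 and 0.893. Xist measured 5.35 ± 0.98 in the knockout and 4.57 ± 0.05 in the wild type, and the Y-linked genes Eif2s3y, Kdm5d and Uty differed by -0.13 to 0.16.

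**Figure D2:**
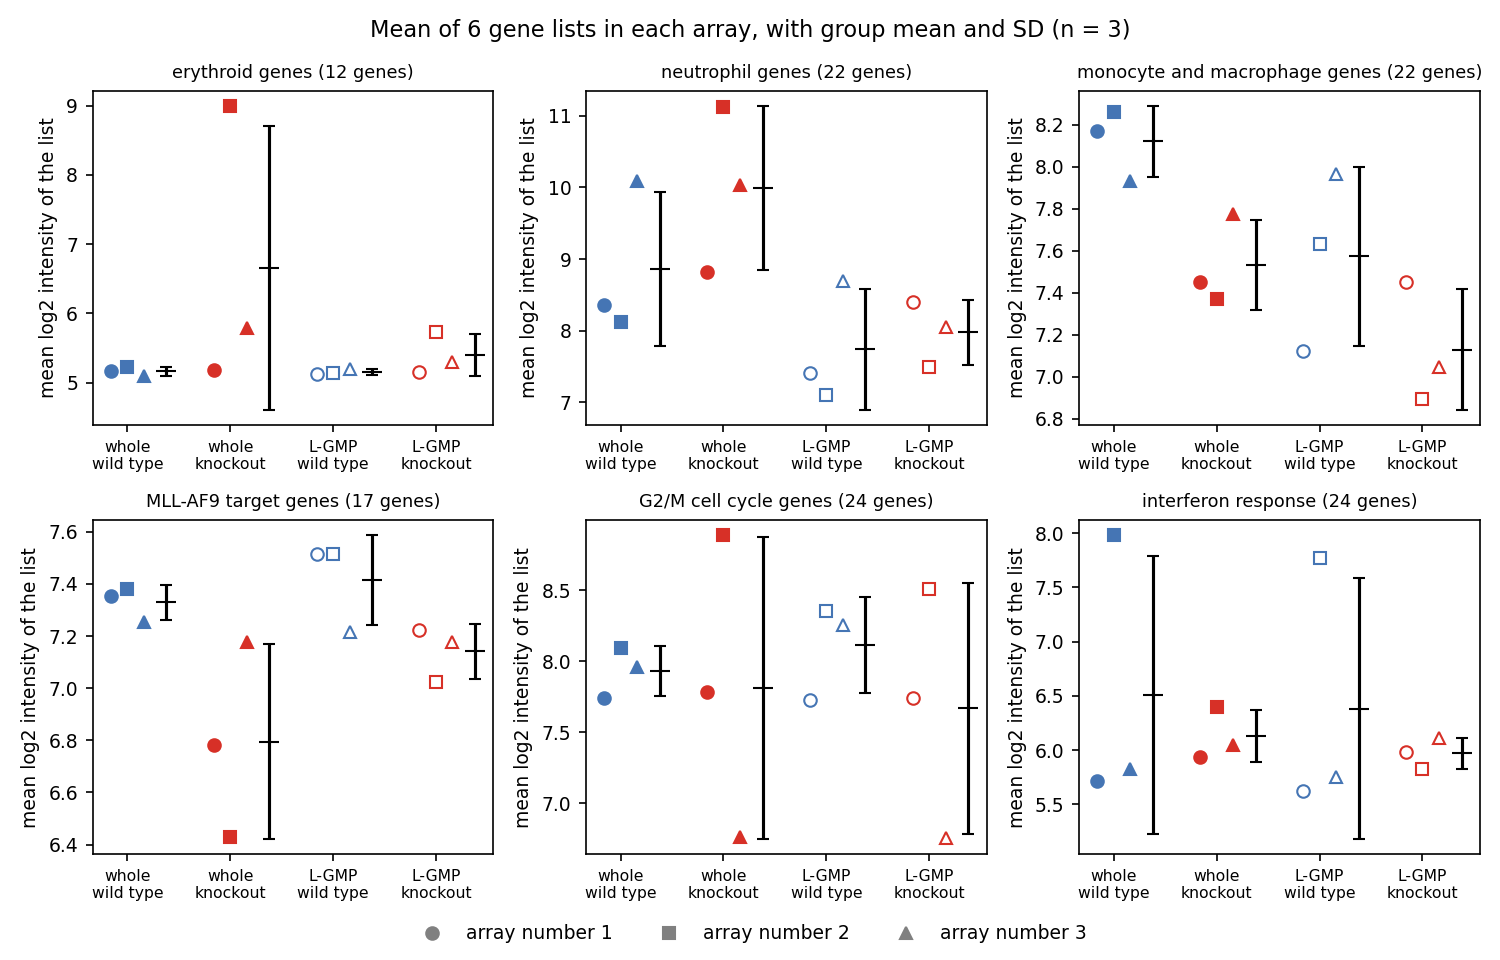
Mean log2 intensity of 6 gene lists in each of the 12 arrays, by group (filled symbols for whole leukemia, open for L-GMP, blue for wild type, red for knockout; the symbol gives the array number), with bars for the group mean and SD (n = 3). The erythroid mean was 9.0 in knockout whole leukemia array 2 against 5.10 to 5.79 in the other 5 whole leukemia arrays, and the interferon means of both number-2 wild-type arrays were 7.98 and 7.77.

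Camera called 9 lists in whole leukemia, 3 higher and 6 lower, and 0 with an estimated correlation, as did fry. Monocyte and macrophage genes were lower in 19 of 22 members (adjusted p = 3.61e-06; adjusted p = 0.455 with an estimated correlation), 5 of them called when adjusted over the list alone and 0 over all genes. The monocyte chemokine receptor genes Ccr2 (-0.89, SE 0.24) and Cx3cr1 (-0.78, SE 0.22), Mpeg1 (-1.0) and the factor XIII gene F13a1 (-1.24) led this list. MLL-AF9 target genes were lower in 15 of 17 members (adjusted p = 0.000358; adjusted p = 0.455 with an estimated correlation), led by Mef2c (-1.97, SE 0.56), Hoxa5 (-0.84), Meis1 (-1.10) and Hoxa9 (-1.01). Erythroid genes were higher in 12 of 12 members (adjusted p = 2.31e-06; adjusted p = 0.769 with an estimated correlation), such as the carbonic anhydrase gene Car2 (2.98, SE 1.31), Rhag (2.15) and the erythroid regulator gene Klf1 (0.55). Neutrophil genes were higher in 21 of 22 (adjusted p = 8.44e-06; adjusted p = 0.86 with an estimated correlation), such as Ly6g (2.66, SE 0.83) and Retnlg (3.48, SE 1.16). These 4 lists were called without each of the 12 arrays. Yet the erythroid mean of knockout whole leukemia array 1 (5.18) lay below that of wild-type array 2 (5.22). The neutrophil mean of wild-type whole leukemia array 3 (10.09) lay above those of knockout arrays 1 and 3 (8.82 and 10.03). Without knockout whole leukemia array 2 the erythroid and neutrophil lists had camera adjusted p-values of 0.0141 and 0.0314. The size of both differences rested on that array, since without it the mean difference was 0.32 in place of 1.5 for the erythroid list and 0.57 in place of 1.13 for the neutrophil list. Car2 measured 11.35 in it and at most 6.96 in the other 5 whole leukemia arrays.

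The sorting gate list was lower in whole leukemia (adjusted p = 0.014; adjusted p = 0.455 with an estimated correlation), with Cd34 as the member called when adjusted over the list alone, and was not called with the 2 compared groups alone (0.079). Hypoxia genes were lower in 15 of 18 members, with the collagen hydroxylase gene P4ha1 (-0.83, SE 0.17) called over the list alone (adjusted p = 0.014; adjusted p = 0.769 with an estimated correlation). That call was lost without wild-type array 3 (0.0793) or knockout array 2 (0.0991) of whole leukemia. MYC targets and ribosome biogenesis genes were lower in 20 of 22 members, such as Polr1a (-0.34, SE 0.11), and tricarboxylic acid cycle genes in 14 of 17, such as the isocitrate dehydrogenase genes Idh3g (-0.45, SE 0.15) and Idh3b (-0.43) (both adjusted p = 0.0139; adjusted p = 0.86 with an estimated correlation). Without knockout whole leukemia array 2 the MYC list turned upward (adjusted p = 0.594) and the tricarboxylic acid cycle list was not called (0.17). Without knockout array 3 both had 0.127, without wild-type array 1 the first had 0.0719, and without wild-type array 3 the second had 0.051. B cell genes were higher in 11 of 13 members, such as the immunoglobulin gene Ighm (1.30, SE 0.68) (adjusted p = 0.0427; adjusted p = 0.611 with an estimated correlation), and not past the threshold without whole leukemia arrays wild-type 1 or 2 or knockout 1 or 2, or L-GMP arrays wild-type 1 or 3 or knockout 2 (0.0547 to 0.281). The B cell call was lost too with the lowest 50% left out (0.266), the 2 compared groups alone (0.113) and array weights (0.245). Without both number-2 knockout arrays the tricarboxylic acid cycle (0.102) and hypoxia (0.0788) lists were not called. Interferon genes (-0.38, adjusted p = 0.135), glycolysis genes (-0.07, 0.182) and fatty acid oxidation genes (-0.04, 0.77) were not called.

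In wild-type leukemia the comparison of L-GMP with whole leukemia asks what sets the leukemia-initiating fraction apart from the bulk. By camera with the preset correlation, wild-type L-GMP had lower levels of neutrophil, monocyte, inflammatory and lysosomal genes, and higher levels of MYC target, G1/S, DNA repair and respiratory chain genes. All 8 calls were lost with an estimated correlation (adjusted p = 0.96), and that of the respiratory chain also without any of 4 arrays. L-GMP were sorted as lineage-negative and whole leukemia was not, so lower neutrophil and monocyte genes may not be independent of the sort. Cd34, a gate marker, measured 9.76 ± 0.25 log2 units (SD, n = 3) in L-GMP and 8.74 ± 0.56 in whole leukemia, a difference of 1.03 (SE 0.37, higher in 3 of 3 arrays, adjusted p = 1). Kit (0.56), Fcgr3 (-0.32) and Fcgr2b (-0.05) had adjusted p = 1 as well. Limma called 0 genes, as it did with a trended and robust variance and with array weights. There were 443 genes with an unadjusted p under 0.05, 164 higher and 279 lower, where 887 would be met by chance, and 10.3% of genes had no overlap (10% by chance). Both chance values take all arrays as independent, although wild-type arrays of equal number correlated across the populations (0.36, 0.62 and 0.3). A count below them thus says little about how far the populations differ. The genes of lowest p with lower values in L-GMP, all at adjusted p = 1, were Ms4a8a (-1.50, SE 0.33), the proteoglycan gene Vcan (-1.34, SE 0.32), the lysosomal sulfatase gene Ids (-0.55), the calcium sensor gene Stim1 (-0.51) and the drug transporter gene Abcc3 (-0.39). Those with higher values were Plekhn1 (0.48), Prss3 (0.41), Ctrl (0.39), Ccdc77 (0.47) and N4bp2l2 (0.36). Prkaa1 (-0.10) and Prkaa2 (0.12) differed little, Xist by 0.05, and Eif2s3y, Kdm5d and Uty by 0.09, 0.25 and 0.30.

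Camera called 8 lists in that comparison, 4 higher and 4 lower in L-GMP, each at an adjusted p = 0.96 with an estimated correlation, where 0 were called, as with fry. All 22 neutrophil genes were lower, among them the alarmin gene S100a9 (-1.74, SE 0.84), Fpr2 (-1.80) and the collagenase gene Mmp8 (-2.26) (adjusted p = 2.89e-07; 0.0946 without wild-type whole leukemia array 3, whose neutrophil mean was 10.09 against 8.36 and 8.13 in arrays 1 and 2). Monocyte and macrophage genes were lower in 19 of 22 members (adjusted p = 2.89e-07), with Vcan called when adjusted over the list alone, Cx3cr1 at -0.63 and Ccr2 at -0.65. All 22 MYC target genes, such as Npm1 (0.30, SE 0.18) (adjusted p = 4.82e-05), and all 22 G1/S genes, such as Ung (0.57, SE 0.21) and Mcm5 (0.34) (adjusted p = 9.41e-05), were higher. These 2 lists and the monocyte list were called without each of the 12 arrays. Inflammatory cytokine genes were lower in 15 of 19 members, such as Icam1 (-0.31, SE 0.13) and Ccl6 (-0.95) (adjusted p = 0.00134; 0.0651 without wild-type whole leukemia array 1). Autophagy and lysosome genes were lower in 24 of 29, such as the cathepsin genes Ctsl (-0.65, SE 0.27) and Ctsb (-0.63) (adjusted p = 0.00237; 0.113 without wild-type L-GMP array 1). Oxidative phosphorylation genes were higher in 36 of 46, such as Cox7b (0.22, SE 0.14) (adjusted p = 0.0105), and lost the call without wild-type whole leukemia array 1 (0.133) or 3 (0.0962) or wild-type L-GMP array 2 (0.756) or 3 (0.296), or both number-2 wild-type arrays (0.249). DNA repair genes were higher in 17 of 20, such as Msh6 (0.23, SE 0.16) (adjusted p = 0.0167; 0.1 without wild-type whole leukemia array 3 and 0.437 without wild-type L-GMP array 2, 0.407 without both number-2 wild-type arrays). G2/M genes were higher in 23 of 24 members and not called (adjusted p = 0.244).

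In AMPK-deficient leukemia the same comparison of L-GMP with whole leukemia was made. By camera with the preset correlation, knockout L-GMP had lower levels of neutrophil, erythroid, inflammatory, monocyte and B cell genes, and higher levels of MYC target, tricarboxylic acid cycle, respiratory chain, stem cell, sorting gate and unfolded protein response genes. All 11 calls were lost with an estimated correlation (adjusted p = 0.197 or above), and the respiratory chain list turned downward without knockout L-GMP array 2 (0.754). Only L-GMP were sorted as lineage-negative, so lower neutrophil, erythroid, monocyte and B cell genes may not be independent of the sort. The same holds for the sorting gate and stem cell lists, which hold the sort marker gene Cd34. Cd34 measured 9.67 ± 0.22 log2 units (SD, n = 3) in L-GMP and 6.41 ± 0.78 in whole leukemia, a difference of 3.26 (SE 0.37, 9.55-fold, higher in 3 of 3 arrays). Acads, of short-chain fatty acid oxidation, measured 7.46 ± 0.04 and 6.71 ± 0.15, a difference of 0.75 (SE 0.09, 1.68-fold). Neither passed (adjusted p = 0.0743 and 0.093). Limma called 0 genes, with a trended and robust variance 1 and with array weights 0. There were 1312 genes with an unadjusted p under 0.05, 764 higher and 548 lower, where 887 would be met by chance, and 10.2% had no overlap (10% by chance). Cd34 was called with a trended and robust variance (adjusted p = 0.0177) and when the lowest 50% of probe sets were left out (0.0302). With the random replicate block limma called both Cd34 (0.0261) and Acads (0.0488), although the knockout numbers did not meet the criterion for pairs. Without knockout whole leukemia array 1 the count was 40, 13 higher and 27 lower.

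The further genes of lowest p in that comparison, at adjusted p = 0.671, had higher values in knockout L-GMP for Pcp4l1 (1.16, SE 0.20), the glutathione transferase gene Gstp1 (0.89, SE 0.16) and Rad9a (0.43). Lower values were found for Klra2 (-2.07, SE 0.41), the lysosomal transporter gene Slc15a3 (-1.91), Resf1 (-1.16), the receptor gene Igf2r (-0.92) and the inhibitory receptor gene Lilrb4a (-3.23, SE 0.73). Of the other gate genes, Kit had a difference of 1.14 (SE 0.48), Fcgr2b of 0.46 and Fcgr3 of 0.08. Prkaa1 (-0.27) and Prkaa2 (0.00) differed little, as did Xist (-0.03), Eif2s3y (-0.01), Kdm5d (0.11) and Uty (0.03).

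Camera called 11 lists there, 6 higher and 5 lower in L-GMP, and 0 with an estimated correlation. Neutrophil genes were lower in all 22 members (adjusted p = 7.25e-14; adjusted p = 0.523 with an estimated correlation), 5 of them called when adjusted over the list alone, such as Retnlg (-4.60, SE 1.16), Mmp8 (-3.88) and Ly6g (-2.91). The sorting gate list was higher in 4 of 4 members (adjusted p = 0.00123; adjusted p = 0.197 with an estimated correlation) and was the 1 list that fry called (0.00536), with Cd34 called over the list alone; its genes encode the markers that L-GMP were sorted on. All 22 MYC target genes were higher (adjusted p = 3.07e-08; adjusted p = 0.625 with an estimated correlation), such as the spermidine synthase gene Srm (1.04, SE 0.42) and Pa2g4 (0.61). All 17 tricarboxylic acid cycle genes were higher (adjusted p = 2.6e-05; adjusted p = 0.625 with an estimated correlation), such as Idh3g (0.53, SE 0.15) and Suclg1 (0.54). Inflammatory cytokine genes were lower in 15 of 19 members (adjusted p = 0.000432; adjusted p = 0.625 with an estimated correlation), 2 of them called over the list alone, with the interleukin 1 receptor antagonist gene Il1rn at -1.26 (SE 0.29) and Ccl6 at -1.75 (SE 0.42). These 5 lists were called without each of the 12 arrays. With both number-2 knockout arrays left out 6 lists were called, and the MYC (0.109), tricarboxylic acid cycle (0.592) and inflammatory (0.617) lists were not among them. Without knockout L-GMP array 3 the count was 17.

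Erythroid genes were lower in 12 of 12 members in knockout L-GMP than in knockout whole leukemia (adjusted p = 2.6e-05; adjusted p = 0.677 with an estimated correlation), with the band 3 gene Slc4a1 at -2.13 (SE 1.15), and not past the threshold without knockout whole leukemia array 2 (0.158), in which Slc4a1 measured 11.58. Oxidative phosphorylation genes were higher in 39 of 46, such as Cox5a (0.46, SE 0.15) (adjusted p = 0.00258; adjusted p = 0.751 with an estimated correlation), but turned downward without knockout L-GMP array 2 (0.754) and were not called without knockout whole leukemia array 2 (0.0954) or with array weights (0.206). Stem and progenitor genes were higher in 14 of 19, such as Gata2 (0.79, SE 0.25) and Angpt1 (1.28) beside Cd34, which was the member called over the list alone (adjusted p = 0.00422; adjusted p = 0.523 with an estimated correlation). Without knockout whole leukemia array 1 or knockout L-GMP array 2 the list had 0.0731 and 0.0959. Unfolded protein response genes were higher in 15 of 17, such as the calreticulin gene Calr (0.94, SE 0.38) (adjusted p = 0.00934; adjusted p = 0.734 with an estimated correlation), with 0.691 without knockout whole leukemia array 2, 0.155 without knockout L-GMP array 1 and 0.617 without both number-2 knockout arrays. Monocyte genes were lower in 14 of 22, such as Fn1 (-2.43, SE 0.78) and Cybb (-1.65) (adjusted p = 0.00934; adjusted p = 0.677 with an estimated correlation), with 0.0887, 0.054 and 0.0776 without knockout whole leukemia array 3 and knockout L-GMP arrays 2 and 3, and 0.057 with array weights. B cell genes were lower in 9 of 13, such as Ighm (-1.75, SE 0.68) (adjusted p = 0.0244; adjusted p = 0.523 with an estimated correlation), and lost the call without knockout arrays 1 or 2 of whole leukemia or of L-GMP (0.054 to 0.158). It was lost too with the lowest 50% left out (0.202), the 2 compared groups alone (0.0611) and array weights (0.142).

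The genotype-by-population interaction asks whether the effect of AMPK loss differs between L-GMP and whole leukemia. By camera with the preset correlation, the knockout difference was more positive in L-GMP for tricarboxylic acid cycle, unfolded protein response, stem cell and sorting gate genes, and more negative for erythroid and neutrophil genes. All 6 calls were lost with an estimated correlation (adjusted p = 0.218 or above). Cd34 had an interaction of 2.23 log2 (SE 0.53), from -0.09 in L-GMP and -2.32 in whole leukemia, and did not pass (adjusted p = 1). Limma called 0 genes, 0 with a trended and robust variance and 0 with array weights. There were 365 genes with an unadjusted p under 0.05, 213 positive and 152 negative, where 887 would be met by chance. That chance value takes all arrays as independent, which wild-type arrays of equal number in both populations were not. The genes of lowest p, all at adjusted p = 1, were Acads (0.70, SE 0.13), Pcp4l1 (1.43), Snapc2 of small nuclear RNA transcription (0.81), Rad9a (0.50) and the synaptic adhesion gene Nlgn2 (0.80) among positive ones. Negative ones were Tigd3 (-0.65), Lce3a (-0.52), N4bp2l2 (-0.53), the calcium-binding protein gene Cabp1 (-0.47) and Rdh16f2 (-0.40). The interaction of Prkaa1 was -0.17 (SE 0.34) and that of Prkaa2 -0.12. Kit (0.58), Fcgr3 (0.40), Fcgr2b (0.52), Xist (-0.08), Eif2s3y (-0.10), Kdm5d (-0.14) and Uty (-0.27) had adjusted p = 1 too.

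Camera called 6 lists in the interaction, 4 positive and 2 negative, and 0 with an estimated correlation, as did fry. The sorting gate list was positive in 4 of 4 members (adjusted p = 0.00243; adjusted p = 0.218 with an estimated correlation) and was called without each of the 12 arrays, and Cd34 was called when adjusted over the list alone. L-GMP of both genotypes were sorted on the proteins that these genes encode, so this interaction may not be independent of the sort. The other 5 lists had an adjusted p = 0.834 with an estimated correlation. Of these, the stem and progenitor list holds Cd34, and the neutrophil and erythroid lists hold genes of mature cells, while only L-GMP were sorted as lineage-negative. Those interactions may not be independent of the sort either. Tricarboxylic acid cycle genes were positive in 17 of 17 members, such as Idh3g (0.62, SE 0.21) and Idh3b (0.57) (adjusted p = 0.000775; 0.185 without knockout L-GMP array 2). Unfolded protein response genes were positive in 16 of 17, such as Pdia3 (0.50, SE 0.34) and Calr (0.71) (adjusted p = 0.00364; 0.0583 without wild-type whole leukemia array 1, 0.494 without knockout whole leukemia array 2 and 0.0853 without knockout L-GMP array 1). Stem and progenitor genes were positive in 16 of 19, such as Erg (0.93, SE 0.40) and Cd93 (0.78), with Cd34 called over the list alone (adjusted p = 0.0267; 0.0507 and 0.185 without wild-type array 3 and knockout array 1 of whole leukemia, 0.0657 and 0.283 without wild-type array 3 and knockout array 2 of L-GMP, and 0.0932 with array weights). When both number-2 knockout arrays were left out, the tricarboxylic acid cycle (0.861), unfolded protein response (0.15), stem and progenitor (0.142) and erythroid (0.0524) lists were not called, and the neutrophil list turned (0.873). Erythroid genes were negative in 12 of 12, such as Sptb (-1.63, SE 1.18) (adjusted p = 0.000252; 0.494 without knockout whole leukemia array 2). Neutrophil genes were negative in 20 of 22, such as Ly6g (-2.67, SE 1.17) (adjusted p = 0.00243), and lost the call without wild-type arrays 1 (0.0583) or 2 (0.0993) or knockout array 2 (0.473) of whole leukemia, or wild-type array 3 (0.271) or knockout array 2 (0.185) of L-GMP. The number of called lists was 10 without wild-type array 2, knockout array 1 or knockout array 3 of whole leukemia or without wild-type L-GMP array 2, and 12 without knockout L-GMP array 3.

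Across the 17749 genes, which are not independent replicates, the knockout difference in L-GMP correlated with that in whole leukemia at Pearson r = 0.44 and Spearman rho = 0.29, with the same sign in 58.6% of genes. The populations share no array. Stag3, 1700080G11Rik, Mef2c, Dennd5b (-2.12 in L-GMP), Fn1 and Tns1 (-1.15 in L-GMP) lay lower, and Msantd3 and Nkg7 higher, on average in the knockouts of both. Differences between 1 knockout and 1 wild-type array in L-GMP correlated with those of the same-numbered arrays in whole leukemia at 0.37 on average over 9 pairs. Over the 36 pairs with both numbers different the average was 0.072. When the 6 combinations of genotype and number were regrouped 3 against 3, the real grouping gave 0.44 and the other 9 gave 0.19 to 0.45. A value as high came from 2 of the 10, the real one included.

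**Figure D3:**
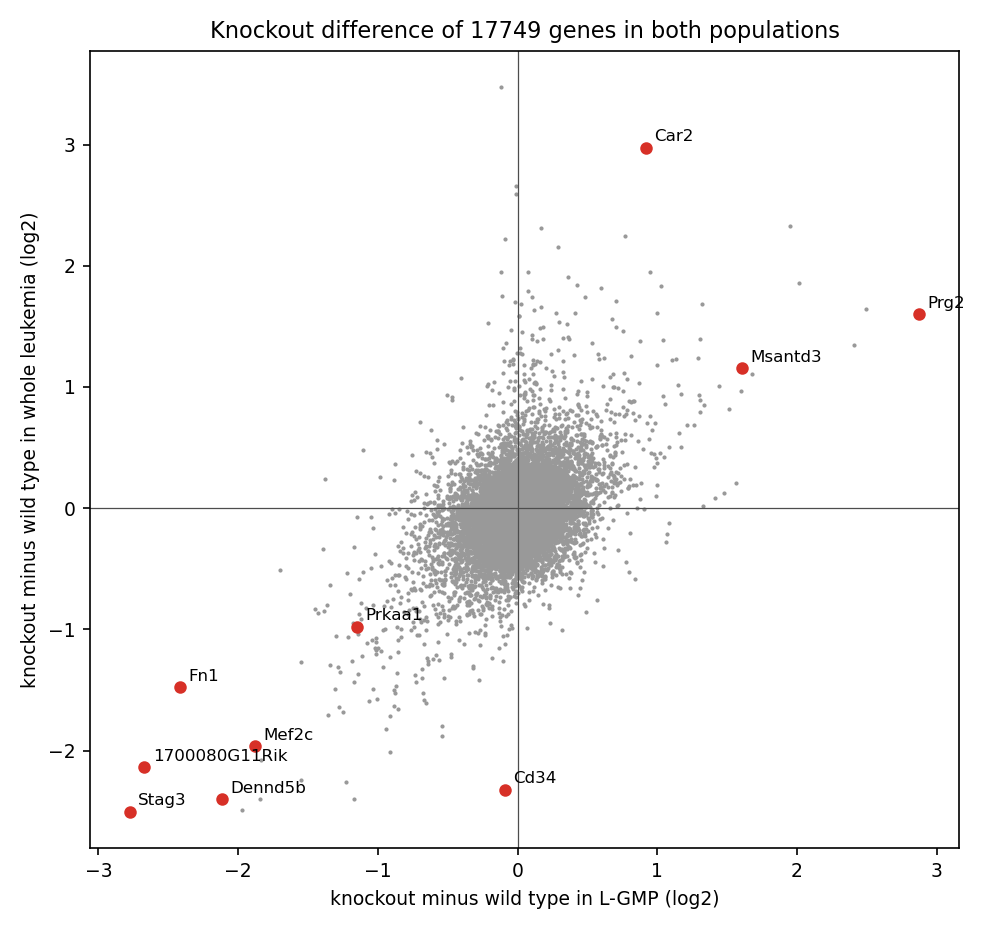
Knockout minus wild-type difference (log2) of 17749 genes in L-GMP (x axis) and whole leukemia (y axis), 1 grey point per gene, with 10 genes in red. Stag3 and 1700080G11Rik lay at -2.77 and -2.67 in L-GMP and at -2.50 and -2.14 in whole leukemia, and Cd34 at -0.09 and -2.32.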

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

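The tests of normal cells, normalization and loss of AMPK below were chosen after the results were seen, and the counts over other splits of the arrays before. Groups of 3 were not tested for a single sample far from the others. The results below stand here because a test of the interaction, or every array of both populations, set the knockout difference in L-GMP apart from that in whole leukemia.

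By the camera test of the interaction with the preset correlation, 6 lists were called, at mean log2 values of 0.31 for the tricarboxylic acid cycle, 0.34 for the unfolded protein response, 0.45 for stem and progenitor genes, 0.93 for the sorting gate, -0.89 for neutrophil genes and -1.26 for erythroid genes. All 6 lost their call with an estimated correlation (lowest adjusted p = 0.218), and fry called 0. Those of the sorting gate, stem and progenitor, neutrophil and erythroid genes may also not be independent of the L-GMP sort. Without knockout whole leukemia array 2 the means were -0.08 for erythroid genes, -0.32 for neutrophil genes and 0.10 for the unfolded protein response. The size of these means rested mostly on that array. Those of the tricarboxylic acid cycle (0.21), stem and progenitor (0.50) and sorting gate (0.87) lists moved less. Without knockout L-GMP array 2 the camera calls of the tricarboxylic acid cycle (adjusted p = 0.185) and stem and progenitor (0.283) lists were lost. Its tricarboxylic acid cycle mean was 8.56 against 8.163 and 7.945 in knockout L-GMP arrays 1 and 3. Its stem and progenitor mean was 6.94 against 6.29 and 6.34.

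Among 56 named genes, 7 had every knockout array above every wild-type array in 1 population and below in the other. Their interaction values were 0.70 for Acads, 1.43 for Pcp4l1, 0.82 for Gstp1, 0.81 for Snapc2, 0.80 for Nlgn2, -0.65 for Tigd3 and -0.52 for Lce3a, each at a limma adjusted p = 1, and most of them had been named for a low interaction p. Over all 17749 genes, 34 had such opposite moves and 218 had like moves in both populations, where independent populations would give 88.7 of each by chance. Opposite moves were thus fewer, and like moves more, than that value, which takes the populations as independent although wild-type arrays of equal number correlated across them (0.36, 0.62 and 0.3). These counts were not tested.

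Erythroid genes were far higher in knockout whole leukemia array 2 than elsewhere, with a mean of 9.0 against at most 5.79, and neutrophil genes were highest there, at 11.12 against at most 10.09. That array's median log2 value was 5.297, against 5.246 to 5.297 in the other 5 whole leukemia arrays. This argued against a scaling of the whole array in the deposited values. After quantile normalization its erythroid list still lay 3.74 log2 above the other 5 whole leukemia arrays (SD 0.273), against 3.71 as deposited. With medians already alike, that test could change little and adds no support. Normal hematopoietic cells mixed into that sample, which the GFP sort would remove if they were untransduced, stayed open. Its MLL-AF9 target mean of 6.43 lay below the 6.78 to 7.38 of the other 5, as a mixture would give. The other knockout arrays, at 6.78 and 7.18, also lay below the lowest wild-type array (7.25). A low value thus cannot tell a mixture from the genotype. That array's T and NK mean (5.629) and mast cell, basophil and eosinophil mean (6.913) exceeded those of the other 5 (at most 5.317 and 5.988). So, narrowly, did the B cell (6.151 against 6.115) and megakaryocyte (5.443 against 5.379) means. The monocyte mean (7.372) lay below them, and the dendritic cell and stromal means among them. Xist was highest of all arrays there, then in knockout L-GMP array 2. Whether a mixture gave these values was not tested. Abundant red cell genes were high in knockout whole leukemia array 2, Slc4a1 at 11.58 and Car2 at 11.35 (at most 6.83 and 6.96 in the other 5), and 0 of 12 erythroid, 0 of 22 neutrophil and 1 of 17 MLL-AF9 target genes stand in another list. Loss of AMPK cannot be told apart from the state of that sample, since 2 of 3 knockout arrays had an erythroid mean above the highest wild-type array, at 9.0 and 5.79 against 5.22.

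Splits of the same 6 arrays into 3 and 3 number 10, the real one included, and are too few for a share under 0.05. For L-GMP by genotype, the real split called 1 gene and 9 lists, the highest other split 0 genes and 13 lists, and 1 and 6 of 10 splits reached the real counts. For whole leukemia by genotype, the real counts were 0 and 9, the highest others 3 and 18, and 10 and 9 splits reached the real counts. For the wild-type populations, the real counts were 0 and 8, the highest others 0 and 10, and 10 and 2 splits reached the real counts. Of the 4 splits there that part all 3 numbered pairs, the real one called 8 lists and the other 3 called 0 to 3 lists. For the knockout populations, the real counts were 0 and 11, the highest others 253 and 18, and 10 and 8 splits reached the real counts. The split with 253 genes set knockout whole leukemia array 1 and knockout L-GMP arrays 1 and 2 against the other 3. What lies behind that count was not tested. For the interaction, 93 of 100 random splits called as many lists as the real 6 (highest other 22), so chance cannot be excluded for the lists. A real count of 0 genes is reached by every split whatever the data, here by 100 of 100 (highest other 1), and decides nothing.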

How the results depend on the processing

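The tests without both number-2 arrays of a genotype and with a block by genotype and number were chosen after the results were seen, and the other alternatives before. Of the counts of called genes and lists, 210 were the same within 1.5 times, 17 higher and 27 lower. Of the values of called lists, 915 kept their call and direction, 169 lost the call and 10 turned. Of those of named genes, 1724 kept their side, 15 gained and 15 lost a call and 17 turned. Quantile normalization and median centring moved no count by over 1.5 times. The cause was not tested for any change below, except that fewer arrays widen the errors.

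Called genes in L-GMP by genotype numbered 0 with no filter on dim genes, 2 with trend and robust variance, 0 with only the 2 groups compared, 2 with the mean of all probe sets, 4 with array weights, 0 with the replicate block (lowest adjusted p = 0.176), 0 without both number-2 wild-type arrays and 0 to 2 leaving out 1 array. In whole leukemia they numbered 1 without both number-2 knockout arrays and 0 to 1 leaving out 1 array. In the knockout populations they numbered 1 with the lowest 50% left out, 1 with trend and robust variance, 2 with the random replicate block and 0 to 40 leaving out 1 array.

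Called lists numbered 0 with an estimated correlation in all 5 comparisons, and with fry 0 in 4 and 1 in the knockout populations. They numbered 4 in L-GMP by genotype without both number-2 wild-type arrays and 6 in the knockout populations without both number-2 knockout arrays. Leaving out 1 array, they numbered 3 to 13 in L-GMP and 8 to 12 in whole leukemia by genotype, 6 to 11 in the wild-type populations, 9 to 17 in the knockout populations and 4 to 12 in the interaction.

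Lists that turned have these adjusted p-values over arrays left out: in L-GMP by genotype DNA repair 0.000295 to 0.993, G1/S 5.97e-05 to 0.864, G2/M 7.61e-11 to 0.997 and interferon 0.000316 to 0.338, MYC targets in whole leukemia 1.54e-09 to 0.594, and oxidative phosphorylation in the knockout populations 2.71e-06 to 0.754. Without both number-2 wild-type arrays interferon genes turned upward in L-GMP (0.0197). Without both number-2 knockout arrays MYC targets in whole leukemia (0.546), oxidative phosphorylation in the knockout populations (0.0681) and neutrophil genes in the interaction (0.873) turned.

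Genes near 0 changed sign. Leaving out 1 array, values in L-GMP by genotype ran from -0.067 to 0.063 for Prkaa2, -0.21 to 0.051 for Cd34, -0.084 to 0.18 for Fcgr3 and -0.17 to 0.094 for Fcgr2b. Those of Fcgr2b in the wild-type populations ran from -0.20 to 0.19 and those of Fcgr3 in the knockout populations from -0.015 to 0.22. Without both number-2 wild-type arrays Cd34 had 0.051 and Fcgr3 -0.084 in L-GMP, and without both number-2 knockout arrays Fcgr2b had 0.077. With array weights Fcgr2b had 0.15 in L-GMP and Fcgr3 -0.076 in the knockout populations.

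Equal numbers in the 2 genotypes correlated at 0.031, -0.1 and 0.06 in whole leukemia and -0.008, 0.19 and 0.0042 in L-GMP, and the knockout populations at 0.13, 0.09 and 0.43. The replicate block gave 0 genes in each of these comparisons, and 9, 9 and 12 lists in L-GMP by genotype, whole leukemia by genotype and the knockout populations. It gave 0 genes and 7 lists in the interaction. It ended the calls of pentose phosphate genes in L-GMP by genotype (0.0792; 0.0516 with the random block) and of B cell genes in whole leukemia by genotype (0.0502). The block by genotype and number ended that of B cell genes in the knockout populations (0.0508). The correlation of the knockout effects of both populations was 0.44 with no filter on dim genes and 0.47 with the lowest 50% left out. Signal over background limits dim genes, since the median probe set mean was 5.28 log2 and genes below 4.72 were left out.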

Other observations

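The tests of the interferon pattern and of loss of AMPK below were chosen after the results were seen, and the test of neighbouring genes before; the genes of the next paragraph were also chosen after their values were seen.

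Several genes differed between samples of 1 genotype in both populations at once. Mef2c, a transcription factor gene among the MLL-AF9 targets, measured 5.59, 7.19 and 5.70 in knockout whole leukemia arrays 1 to 3 and 6.24, 7.95 and 5.61 in knockout L-GMP, against 7.73 to 8.58 in the 6 wild-type arrays. Prg2 measured 11.38 and 11.92 in both number-2 knockout arrays and 8.85 in knockout L-GMP array 1, against 5.45 to 6.59 in the other 9. Eya1, a developmental transcription cofactor gene, measured 9.68 and 9.98 in both number-1 wild-type arrays and 9.25 and 9.02 in both number-3 knockout arrays, against 5.41 to 7.60 in the other 8. Xist measured 6.47 and 5.95 in both number-2 knockout arrays and 4.53 to 5.19 in the other 10, and Eif2s3y lay between 7.65 and 8.43 in all 12. G2/M means were 6.76 and 6.75 in both number-3 knockout arrays and 7.73 to 8.89 in the other 10.

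Interferon response genes were high in both number-2 wild-type arrays, at 7.98 and 7.77, and at 5.62 to 6.4 in the other 10, and Irf7 of that response measured 9.38 and 8.67 in them. T and NK cells mixed into both samples were argued against, since the T and NK list (13 genes, 0 in another list; the GFP sort would remove such cells) lay at -0.089 relative to numbers 1 and 3 (SD 0.056). Of the 4 other wild-type arrays, 0 lay above the highest knockout array of its population. These 4 measured 5.62 to 5.83, below every knockout array of their population. The knockout arrays measured 5.94 to 6.4 in whole leukemia and 5.82 to 6.11 in L-GMP. The number-2 wild-type arrays were set aside for their high values, which by itself leaves lower ones. The other 4 thus cannot decide for or against lower interferon genes through loss of AMPK. Whether AMPK loss matters in the state of the number-2 samples cannot be told, as no knockout array had such values. Without both number-2 wild-type arrays the list turned upward in L-GMP by camera (adjusted p = 0.0197). Those arrays were picked for their high values, so that p-value cannot decide between loss of AMPK and a state of those samples alone.

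Stag3 and 1700080G11Rik were low in all 6 knockout arrays. Deletion of segments holding most of their 20 tested neighbours was argued against, since these had a median knockout difference of 0.024 (SE 0.037). Averaged over both populations, single neighbours of Stag3 ran from -0.21 (Fam20c) to 0.18 (Zfp157). Those of 1700080G11Rik ran from -0.25 (Zmym6) to 0.115 (Dlgap3). A neighbour near background could not fall much, and a shorter deletion that holds none of these genes was not tested. Loss of AMPK cannot be told apart from anything else that follows the genotype groups, as both genes lay below the lowest wild-type array in 6 of 6 knockout arrays.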
